A study of Mus musculus with 8 samples.

How the data were processed

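Colon tissue of 8 mouse samples, 4 labelled Nr4a1 knockout and 4 wild type, was measured by single-cell profiling of fixed RNA with probes (10x Genomics Chromium). Per the labels, pieces of colon were minced, fixed and dissociated before probe hybridisation. Per the file headers, the deposited matrices hold raw UMI counts per gene and barcode written by Cell Ranger 8.0.0, and the values are whole numbers with no normalisation. The matrices are unfiltered: they hold 315250 to 695591 barcodes per library, empty droplets included, so cells were called here. The processing notes of the authors also name Seurat and the builds mm10 and GRCm39 without saying what each was used for, and this leaves open which annotation the probes were matched to. Gene coordinates printed here were looked up by Ensembl ID in GENCODE M21 (GRCm38) and are 1-based. Of 33790 listed features 18381 had counts. Every matrix was assigned to its sample by its name, and 0 columns were left without a sample.

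Barcodes with at least 500 UMIs and 250 genes were kept as cells. Doublets were scored within each library among barcodes of at least 1000 UMIs, from the share of simulated pairs among the nearest neighbours in 30 principal components of 1500 variable genes. The top-scoring 0.8% per 1000 such barcodes were removed, 17675 in all. Clustering used up to 4000 cells per library, 2500 variable genes with Nr4a1 left out, 40 principal components, 15 neighbours and the Leiden algorithm at a resolution of 2; other barcodes took the majority cluster of their 15 nearest clustered cells. A cluster was named from cell type markers by the highest mean log2 fold over the other cells (pseudocount 20 CPM), with at least 3 markers at a log2 fold of at least 1. Clusters whose profile correlated at 0.99 or more with that of barcodes under 100 UMIs were called empty-like and left unnamed, and 3 other clusters reached no name. The larger stem/TA-like cluster, the dendritic-like cluster and the interstitial cell of Cajal-like cluster have none of their markers among their 10 leading genes. Class names rest on RNA alone and carry the ending -like. Heavy free RNA was present in all libraries, so values are given beside the ratio of a class to the empty-droplet profile where a gene's source is in doubt. No correction for free RNA was applied. Before the removal of doublets, median UMIs per kept barcode run from 765 to 1762 and kept barcodes hold 80.7 to 92.9% of the UMIs of a library.

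Counts were summed per library over all kept barcodes (whole colon) and over each class with at least 20 cells in a library. Called doublets were left out of these sums and of the shares of cells. Classes with at least 3 libraries per genotype were tested. Glia-like cells of knockout replicate 3 were too few. Each sum was fitted with edgeR 4.0.16 (TMM normalisation, filterByExpr, robust quasi-likelihood), with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Means and SDs are over libraries in CPM, and SE is the standard error of the log2 fold change. Lists of genes for 30 pathways and programmes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted within a class, and beside it with an estimated correlation and with fry. Shares of cells were compared per library by an exact permutation test, two-sided, over the 70 assignments, within compartments, with Benjamini-Hochberg adjustment within a family. The difference of the knockout effect between stem/TA-like and absorptive colonocyte-like cells was tested by an interaction term with the sample as a term. The choices of comparison, test, list, marker and alternative were made before the data were examined, apart from those said to be chosen later.

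Single genes were named by a rule. Nr4a1 is always given. For each comparison genes are named that have an adjusted p of at most 0.05, a mean of at least 5 CPM in the higher genotype and groups that do not overlap: up to 10 rises and 10 falls, by size, for the whole colon, stem/TA-like and absorptive colonocyte-like cells, and up to 4 and 4 for other classes. For each list up to 4 members with the smallest p in the class discussed are named whether or not they pass. Genes outside this rule were chosen after their values were seen; these are Trim12a, Ly6a, Klhl33, in glia-like cells Serpina3n, Gfap, C1qb, Adamdec1, H2-Ab1 and H2-Eb1, the genes near Nr4a1 and the leading genes of unnamed clusters.

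The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a term, at least 1000 UMIs per cell, doublets kept, Leiden resolution 1, at least 50 cells per library, and leaving out each library in turn. Tests on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison, recovered 37 to 82 of the former and 91 to 100 of the latter with 5 to 21 false calls. The simulated genes varied independently of each other, with no difference between samples besides genotype. These numbers therefore do not give the error rate in the real libraries, where genes vary together. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3. Reads, tissue images and any cell annotation by the authors were not used here. Values of some single genes are not reported here.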

Results

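Colon tissue of 4 Nr4a1 knockout and 4 wild-type C57Bl/6 mouse samples was profiled as single cells with a probe-based kit for fixed RNA, in which pairs of probes, rather than reverse transcription, report each transcript. Nr4a1 (also called Nur77) is an orphan nuclear receptor and immediate early gene. The series title speaks of colonic stem and immune cells, so the question taken here is which genes and cell types differ with the loss of Nr4a1 in these compartments and in the whole colon. Knockout replicates 1 to 4 hold 147287203, 108576121, 23717803 and 254854855 unique molecular identifiers (UMIs), and wild-type replicates 1 to 4 hold 145268323, 146955905, 155976052 and 170311523. Before the removal of doublets, the barcodes kept as cells number 28599, 25611, 4740 and 37741 in the knockouts and 33502, 24219, 32787 and 43534 in the wild types, 230733 in all. Median UMIs per kept barcode, doublets included, are 1579, 1357, 1762 and 1379 in the knockouts and 1068, 1327, 930 and 765 in the wild types. Knockout replicate 3 has the fewest UMIs and kept barcodes. The labels do not state that each library is a separate animal, so p-values measure the spread between these samples.

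Nr4a1 itself (ENSMUSG00000023034; chromosome 15, 101254269 to 101274795, GRCm38) was lower in every knockout library than in every wild-type library of the whole colon. Knockout replicates 1 to 4 held 12.9, 24.0, 16.6 and 17.1 CPM (UMI counts scaled to a common library size) and wild-type replicates 35.9, 26.4, 33.8 and 41.5 CPM. The means were 17.7 ± 4.65 and 34.4 ± 6.25 CPM (SD, n = 4 each), a log2 fold change of −0.96 (SE 0.20). This passed the DESeq2 Wald test (adjusted p = 0.00178) but not the edgeR quasi-likelihood test over 15333 genes (adjusted p = 0.245). Within cell classes Nr4a1 fell in dendritic-like cells, from 72.3 ± 18.1 to 25.8 ± 1.88 CPM (log2 −1.48, SE 0.20, adjusted p = 0.000697), a call kept in every alternative. It also fell in glia-like cells (−2.76, adjusted p = 0.000385, with 3 knockout against 4 wild-type libraries) and in blood endothelial-like cells (−1.24, adjusted p = 0.0369), and in both classes the groups overlap. In glia-like cells wild-type replicate 4 held 25.5 CPM, below every knockout. Without an edgeR call, the groups did not overlap in stem/TA-like cells (14.6 ± 1.88 against 34.5 ± 8.82 CPM, adjusted p = 0.0917) and goblet-like cells (14.6 ± 3.75 against 50.8 ± 18.7 CPM, adjusted p = 0.172). The DESeq2 Wald test called both (adjusted p = 1.37e-07 and 1.71e-07). In lymphatic endothelial-like cells (12.4 ± 4.96 against 32.4 ± 11.3 CPM, edgeR adjusted p = 0.405) the groups did not overlap either. The same held in macrophage/monocyte-like cells (16.7 ± 2.54 against 29.1 ± 6.01 CPM, edgeR adjusted p = 0.246). Neither edgeR nor DESeq2 called Nr4a1 in these last classes. Free RNA in empty droplets carried Nr4a1 at 21.0 CPM in knockouts and 36.5 CPM in wild types. The knockout level within a class ran from 0.0971 (plasma cell-like) to 3.82 times (interstitial cell-like) that of the free RNA. In fibroblast-like cells it was 3.45 times, with 72.4 ± 17.4 CPM in knockouts against 101 ± 21.3 CPM in wild types and no call. The position of the probes relative to the deleted part of the gene is not given in the sources used here, so the remaining counts check the genotype labels only in part. Of the other NR4A genes in the whole colon, Nr4a3 had 5.61 ± 1.51 against 3.32 ± 1.37 CPM (adjusted p = 0.398) and Nr4a2 20.4 ± 6.34 against 17.9 ± 3.94 CPM (adjusted p = 0.759).

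**Figure D1:**
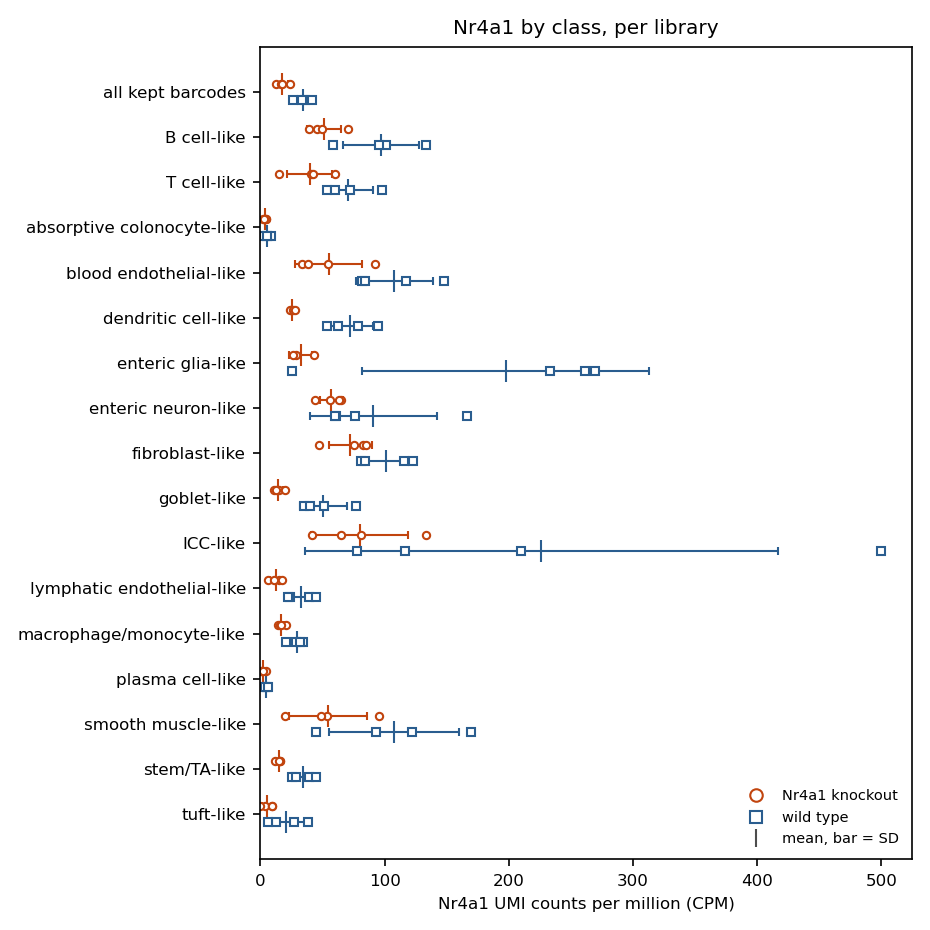
Nr4a1 in CPM (horizontal axis) in each library, for all kept barcodes and for each cell class, with knockouts as circles, wild types as squares, group means as vertical lines and SDs as bars. Over all kept barcodes the 4 knockouts lie between 12.9 and 24.0 CPM, below the 4 wild types at 26.4 to 41.5 CPM.

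In the whole colon, lists of immune and inflammatory genes were higher in knockouts and the stem cell and G2/M lists lower by camera at a preset correlation between genes, while no single gene passed the test. None of these list calls held with an estimated correlation, where the adjusted p was 0.289 for NF-kB, macrophage polarisation, T cell activation and checkpoint and intestinal stem cell, 0.402 for interferon response and 0.517 for G2/M. The lists of NF-kB and inflammatory cytokine genes (29 genes, median log2 fold 0.84) and macrophage polarisation genes (24, median 0.80) rose at the preset correlation (adjusted p = 5.2e-12 each). So did those of T cell activation and checkpoint genes (25, median 0.67) and interferon response genes (33, median 0.66; adjusted p = 9.57e-12 each). Immune-like cells were also more frequent on average in knockouts, at 37.2 ± 11.2 against 26.2 ± 7.16% of named cells, and barcodes outside the immune classes held 75.6 against 84.8% of the UMIs. Without knockout replicate 2 the difference in immune-like cells was 5.78 instead of 11.1 points. Members with their values, none past the test over all genes, include Nos2, the inducible nitric oxide synthase, at 11.9 ± 8.75 CPM in knockouts against 2.79 ± 0.824 in wild types, and the costimulatory receptor Icos at 8.29 ± 2.12 against 3.72 ± 1.56 CPM. The intestinal stem cell list fell at the preset correlation (24 genes, median −0.39, adjusted p = 6.87e-10). In it the Wnt feedback gene Axin2 stood at 40.4 ± 7.32 against 63.1 ± 4.90 CPM and Lrig1, a brake on ErbB signalling, at 69.5 ± 12.0 against 98.1 ± 8.13 CPM (n = 4 each). The G2/M list also fell there (38 genes, median −0.38, none of them positive, adjusted p = 1.18e-11). By edgeR quasi-likelihood 0 of 15333 genes passed after Benjamini-Hochberg adjustment, with the smallest adjusted p at 0.1003. At an unadjusted p under 0.05 there were 1787 genes, 1114 higher and 673 lower, and the DESeq2 Wald test called 224, 140 higher and 84 lower. The groups did not overlap for 770 genes, or 5.02%, where chance gives 2.857% on average over the assignments. Genes vary together between libraries, and another split of the same libraries called 1214 genes, so this difference is no test of genotype. Without knockout replicate 3 or 4 the count of genes called was 6 or 2.

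Adjusted over the list alone, 9 NF-kB, 9 macrophage polarisation, 11 T cell activation and checkpoint and 6 interferon genes were higher and 11 stem cell genes were lower; adjusted over all genes tested, 0 were. Antigen presentation also rose: MHC class I (13 genes, median 0.42, adjusted p = 7.27e-08, and 0.289 with an estimated correlation) with B2m at 212 ± 33.6 against 125 ± 5.24 CPM, and MHC class II (10 genes, median 1.09, adjusted p = 3.52e-06, and 0.445 with an estimated correlation). MHC class II had a median of −0.06 in dendritic-like, 0.05 in macrophage/monocyte-like and 0.19 in B cell-like cells, where it stood at 10.0, 6.25 and 5.62 times the free RNA of knockouts, and it was called only in the last of them (adjusted p = 0.00235, and 0.347 with an estimated correlation). Free RNA in empty droplets moved the same way as the whole colon, with medians of 0.94 for MHC class II, 0.41 for MHC class I, 0.61 for interferon response, 0.68 for macrophage polarisation, 0.54 for T cell activation and checkpoint, 0.42 for NF-kB, −0.32 for intestinal stem cell and −0.24 for G2/M. Metabolic lists fell by less. Cholesterol synthesis had a median of −0.30 (21 genes, adjusted p = 0.000324, and 0.562 with an estimated correlation) and oxidative phosphorylation a median of −0.15 (32 genes, adjusted p = 1.48e-05, and 0.562 with an estimated correlation). The antimicrobial list rose (22 genes, median 0.34, adjusted p = 0.00658, and 0.289 with an estimated correlation), with Reg3g at 14.2 ± 8.79 against 3.61 ± 2.36 CPM. Without knockout replicate 4 or wild-type replicate 1 its median was 0.30 or 0.28 and the call ended. Barcodes that resemble free RNA made up 11.6 ± 14.5% of kept barcodes in knockouts and 39.3 ± 13.4% in wild types (exact permutation test, two-sided, p = 0.0571). Knockout replicate 4 held 32.8%, inside the wild-type range of 24.9 to 56.1%. A cluster among these barcodes has the mast cell markers Mcpt1, Mcpt2, Mcpt4 and Cpa3 among its 10 leading genes, so mast cells may be counted here. Of its reference cells 66.8% came from 1 library.

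**Figure D2:**
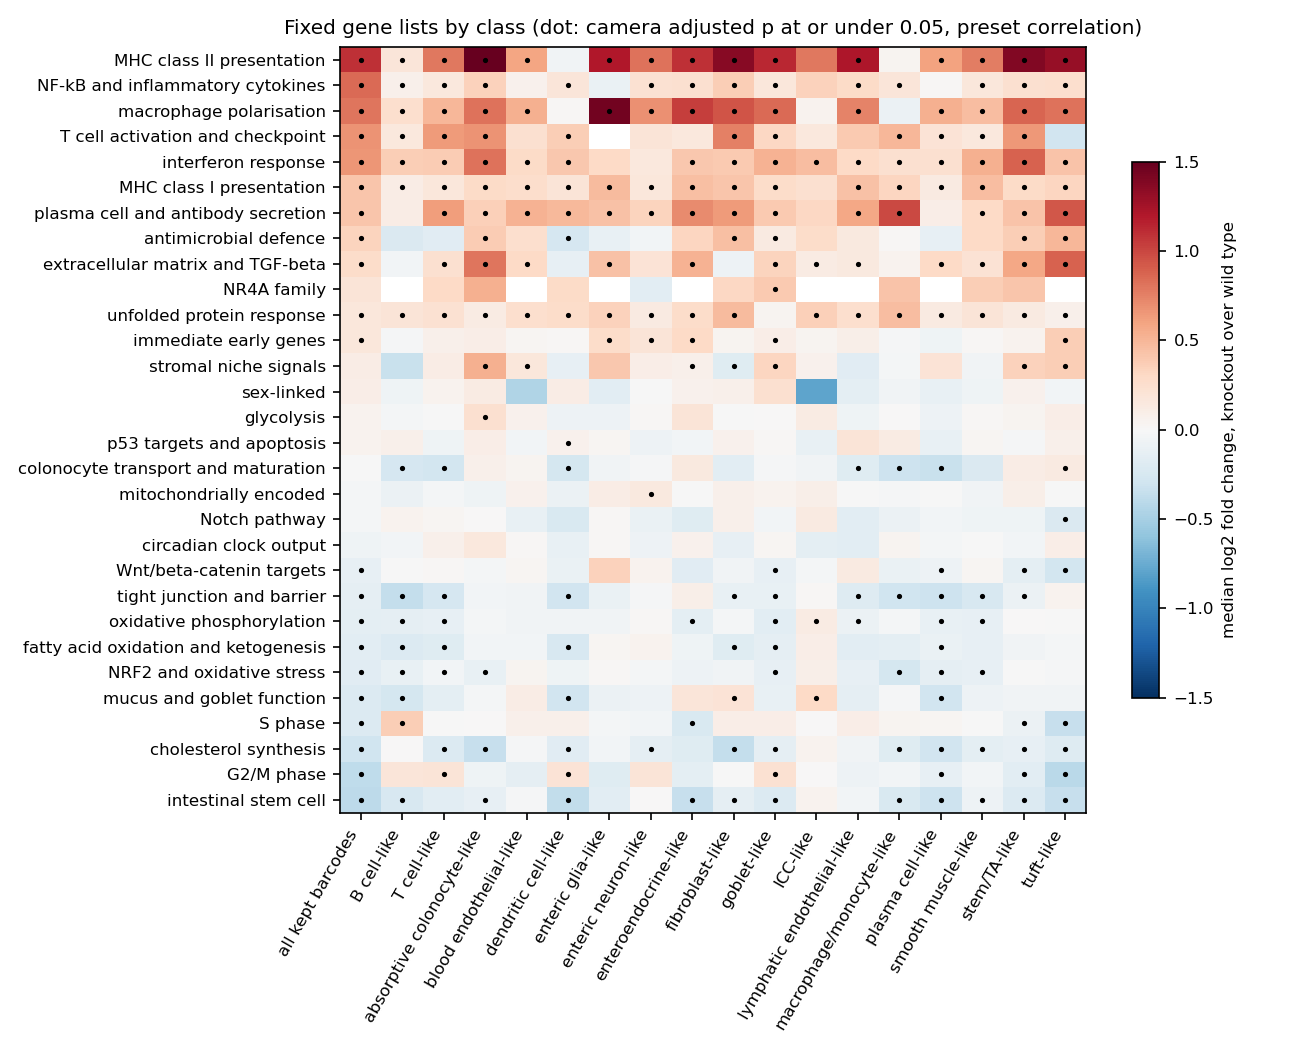
Median log2 fold change, knockout over wild type, of the members of each fixed gene list (vertical axis) in all kept barcodes and in each cell class (horizontal axis), as colour, with a dot where the camera test at the preset correlation gave an adjusted p of at most 0.05 and blank cells for lists not tested. In all kept barcodes the intestinal stem cell list has a median of −0.39 and the interferon response list 0.66.

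In the stem and transit-amplifying (stem/TA-like) class, which bears on the stem cells of the series title, the stem cell and G2/M lists were modestly lower and the interferon, MHC class II and extracellular matrix lists higher in knockouts by camera at the preset correlation. None of these calls held with an estimated correlation, where the adjusted p was 0.289, 0.496, 0.414, 0.373 and 0.373, and 0 of the list genes passed over all genes tested. The larger of the 2 clusters of this class by cell number was named from 6 markers, none among its 10 leading genes. UMIs per barcode were 1.01 times the library median in this cluster and 12.9 times in the other, whose cells thus weigh more in the sums. That other cluster was named from 9 markers. Its 10 leading genes hold 2 of its own markers and the goblet markers Spink4 and Reg4. The intestinal stem cell list fell (23 genes, median −0.20, 2 of them positive): Axin2 had 98.2 ± 9.65 against 131 ± 5.07 CPM, Rgmb 248 ± 34.6 against 332 ± 31.8, Lrig1 162 ± 2.76 against 191 ± 14.02 and Hopx 197 ± 24.7 against 244 ± 18.7 CPM (n = 4 each). The G2/M list fell by a smaller amount (38 genes, median −0.15, none positive), with the centromere histone Cenpa at 39.0 ± 3.88 against 46.9 ± 3.99 CPM. The interferon response list rose (32 genes, median 0.88, all positive), and so did MHC class II (10 genes, median 1.39), whose invariant chain Cd74 had 423 ± 242 against 165 ± 36.7 CPM. The median MHC class II gene in this class stood at 0.132 and 0.0989 times its level in the free RNA of knockouts and wild types, and the median interferon gene at 0.368 and 0.292 times. The extracellular matrix list, whose genes are mostly products of stromal cells, also rose here (33 genes, median 0.57), at 0.129 and 0.108 times the free RNA. Between the free RNA of knockouts and wild types the same genes had medians of 0.94 for MHC class II, 0.62 for interferon, 0.13 for matrix and −0.38 for intestinal stem cell.

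Among single genes of the stem/TA-like class, edgeR quasi-likelihood called 1 higher and 1 lower of 13419 after Benjamini-Hochberg adjustment. Pnn (ENSMUSG00000020994, pinin, a protein of desmosomes and of RNA splicing) rose from 96.8 ± 1.82 to 178 ± 26.3 CPM (log2 0.88, SE 0.10, adjusted p = 0.0242), at about its level in free RNA (0.964 and 1.05 times). Tmem254, a transmembrane protein gene, fell from 99.0 ± 4.94 to 68.1 ± 3.04 CPM (log2 −0.53, SE 0.07, adjusted p = 0.0314). At an unadjusted p under 0.05 there were 1139 genes, and DESeq2 called 78. At the preset correlation camera gave adjusted p values of 6.25e-08 for intestinal stem cell, 8.98e-09 for G2/M, 2.05e-12 for interferon, 8.29e-08 for MHC class II and 1.09e-14 for extracellular matrix. Adjusted over the list alone, 2 stem cell genes were lower and 7 matrix genes higher, against 0 over all genes tested. The count of 2 genes was 1 without knockout replicate 1 or 2, 11 and 13 without knockout replicates 3 and 4, 4 without wild-type replicate 1 and 0 without wild-type replicate 2, 3 or 4.

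Absorptive colonocyte-like cells, the mature cells of the surface epithelium, had higher interferon, MHC and antimicrobial lists and a lower cholesterol synthesis list in knockouts by camera at the preset correlation. None of these calls held with an estimated correlation, where the adjusted p was 0.481 for interferon, 0.332 and 0.454 for MHC class II and I, 0.169 for antimicrobial and 0.454 for cholesterol. The interferon response list rose (32 genes, median 0.81, all positive), with the antiviral enzyme Oas1a at 102 ± 18.5 against 78.4 ± 5.48 CPM, 1.8 and 2 times its level in free RNA. MHC class II rose (10 genes, median 1.64, all positive; adjusted p = 3.42e-07 at the preset correlation), with its median gene at 0.208 and 0.118 times the free RNA, which itself was higher by 0.94 for these genes and by 0.60 for the interferon genes. MHC class I rose (13 genes, 11 positive, median 0.29; adjusted p = 0.00115). The antimicrobial list rose (18 genes, median 0.38), with Nos2 at 39.2 ± 32.2 against 8.44 ± 2.17 CPM, 3.4 and 2.9 times the free RNA, and the dual oxidase factor Duoxa2 at 698 ± 281 against 386 ± 174 CPM. The cholesterol synthesis list fell (21 genes, median −0.34), with Mvk at 20.8 ± 5.82 against 31.7 ± 6.39 CPM. The extracellular matrix list rose in these epithelial cells as well (33 genes, median 0.80, 21 higher adjusted over the list alone and 0 over all genes tested). At the preset correlation camera's adjusted p was 1.27e-29 for matrix (0.169 with an estimated correlation), 2.57e-07 for interferon, 0.00053 for antimicrobial and 6.98e-07 for cholesterol.

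EdgeR quasi-likelihood with Benjamini-Hochberg adjustment called 1 gene higher and 5 lower of 12522 in absorptive colonocyte-like cells, against 1190 at an unadjusted p under 0.05 and 92 by DESeq2. Pnn rose from 51.7 ± 3.66 to 94.5 ± 14.4 CPM (adjusted p = 0.0391). Gvin1, a large interferon-inducible GTPase, fell from 44.9 ± 3.71 to 17.9 ± 5.42 CPM (log2 −1.37, SE 0.17, adjusted p = 0.0391), at 0.309 and 0.248 times the free RNA of knockouts and wild types. Tmem267 fell from 10.2 ± 1.93 to 2.99 ± 0.918 CPM, the purine nucleoside phosphorylase gene Pnp2 from 8.06 ± 0.407 to 3.77 ± 0.476, Tmem254 from 61.7 ± 1.17 to 40.8 ± 3.25 and the unnamed ENSMUSG00000072680 from 67.0 ± 2.49 to 45.2 ± 1.93 CPM (n = 4 each, adjusted p from 0.0391 to 0.0471). The count was 0 without knockout replicate 1 or 2 or any 1 of the 4 wild-type libraries, and 12 without knockout replicate 3. At Leiden resolution 1, or with an unnamed cluster led by Lama3 added to the class, 1 gene was called, a higher one, so all 5 falls lost their calls. With doublets kept 3 genes were called. A test of whether the knockout effect differed between stem/TA-like and absorptive colonocyte-like cells called 0 of 13520 genes by edgeR quasi-likelihood, with 720 at an unadjusted p under 0.05 (DESeq2 was not run on it). The smallest adjusted p was 0.152, and without knockout replicate 3 the test called 2.

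Goblet-like cells shared the direction of the interferon list (27 genes, median 0.53, all positive, adjusted p = 9.07e-12, and 0.509 with an estimated correlation) and of the intestinal stem cell list (23 genes, median −0.21, adjusted p = 0.000458, and 0.509 with an estimated correlation). In free RNA the medians of these genes were 0.61 and −0.38, and the median interferon gene of this class stood at 0.55 and 0.607 times the free RNA of knockouts and wild types. EdgeR quasi-likelihood called 0 of 12399 goblet-like genes and 0 of 10396 tuft-like genes, with 716 and 244 at an unadjusted p under 0.05 and 17 and 3 by DESeq2. In enteroendocrine-like cells 1 gene fell, Gvin1, from 85.6 ± 10.6 to 16.8 ± 8.67 CPM (adjusted p = 0.00143), at 0.289 and 0.473 times the free RNA of knockouts and wild types. Without knockout replicate 3 or 4 the goblet-like count was 2 or 3, and without knockout replicate 4 or wild-type replicate 2 the enteroendocrine-like count was 6 or 2.

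T cell-like cells of knockouts had higher Lag3, Il10 and Icos, and the T cell activation and checkpoint list was higher as a whole (24 genes, 21 positive, median 0.64; camera adjusted p = 6.45e-20 at the preset correlation). With an estimated correlation its adjusted p was 0.0713. Lag3, an inhibitory receptor that binds MHC class II, rose from 55.1 ± 16.6 to 114 ± 12.5 CPM (log2 1.08, SE 0.19, adjusted p = 0.0352). Il10, the anti-inflammatory cytokine, rose from 6.03 ± 2.23 to 24.5 ± 8.20 CPM (log2 1.97, SE 0.36, adjusted p = 0.0461), and Icos from 158 ± 22.2 to 278 ± 40.6 CPM (log2 0.77, SE 0.14, adjusted p = 0.0397). Lag3 and Il10 were 13.6 and 13.8 times as frequent in this class as in the free RNA of knockouts. In the list, whose median gene stood at 17.0 times the free RNA of knockouts, 3 genes were higher over all genes tested and 13 adjusted over the list alone. The interferon list rose too (24 genes, median 0.37; adjusted p = 2.47e-11, and 0.103 with an estimated correlation). The chemokine Ccl8 rose from 5.93 ± 3.86 to 22.8 ± 7.48 CPM at about its free-RNA level (1.09 times in knockouts), and Serpina3n, an acute-phase protease inhibitor, from 28.2 ± 12.2 to 77.1 ± 17.3 CPM below it (0.425 times). Gvin1 fell from 272 ± 35.5 to 94.5 ± 48.7 CPM (adjusted p = 0.00384) and Trim5 from 24.7 ± 8.29 to 3.79 ± 7.58 CPM. For Trim5 knockout replicate 3 held 15.2 CPM and the other knockouts 0, and DESeq2 gave no call (adjusted p = 1.00). EdgeR quasi-likelihood called 8 of 10578 T cell-like genes. Without knockout replicates 1, 3 and 4 the count was 0, 20 and 4, and without wild-type replicates 1, 2 and 3 it was 16, 5 and 5. Lag3 and Il10 both lost their calls without knockout replicate 1 or 4 or wild-type replicate 1 or 3.

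B cell-like cells had 2 genes higher and 2 lower of 10063 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Mybl1, a transcription factor of germinal centre B cells, rose from 3.91 ± 3.70 to 19.7 ± 3.02 CPM (log2 2.70, SE 0.42, adjusted p = 0.0225) and Il9r, the interleukin 9 receptor, fell from 73.4 ± 13.7 to 26.0 ± 8.47 CPM (log2 −1.69, SE 0.21, adjusted p = 0.00233). Pnn rose from 137 ± 19.5 to 247 ± 28.8 CPM and Trim30b fell from 100.4 ± 24.6 to 46.2 ± 19.5 CPM. The S phase list rose in this class (21 genes, 20 positive, median 0.37, adjusted p = 6.15e-07, and 0.347 with an estimated correlation). In plasma cell-like cells only Pnn passed of 11978 genes, from 38.4 ± 2.61 to 77.8 ± 9.76 CPM (adjusted p = 0.00549). The B cell-like count was 1, 0, 10 and 3 without knockout replicates 1 to 4 and 88, 2, 5 and 1 without wild-type replicates 1 to 4. The plasma cell-like count was 2, 2, 11 and 4, then 1, 4, 0 and 1.

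Macrophage/monocyte-like cells of knockouts had higher Tmem26, Pdcd1lg2, Socs2 and Gimap9, and camera at the preset correlation called the unfolded protein response list and the plasma cell and antibody secretion list higher. With an estimated correlation the adjusted p of these lists was 0.307 and 0.247. Tmem26, a transmembrane protein gene, rose from 14.9 ± 4.46 to 43.9 ± 4.95 CPM (log2 1.53, SE 0.21, adjusted p = 0.00232), 18.4 times its free-RNA level in knockouts, and was called in every alternative. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, rose from 10.7 ± 6.05 to 34.4 ± 9.52 CPM (log2 1.76, SE 0.28, adjusted p = 0.0152), 5.18 times its free-RNA level in knockouts. Socs2, a suppressor of cytokine signalling, had 30.6 ± 9.72 against 10.5 ± 2.67 CPM and Gimap9 26.1 ± 10.1 against 9.64 ± 2.00 CPM (adjusted p = 0.0152 each), and both lay near or below free RNA, at 1.10 and 0.899 times in knockouts and 0.367 and 0.499 times in wild types. Trim30d fell from 24.3 ± 5.93 to 6.77 ± 7.47 CPM and Tmem267 from 11.9 ± 2.35 to 2.80 ± 0.884 CPM. The unfolded protein response list rose (18 genes, all positive, median 0.47; adjusted p = 2.95e-13; 12 higher adjusted over the list alone and 0 over all genes). So did the plasma cell and antibody secretion list, which holds markers of another cell type (18 genes, all positive, median 0.99; adjusted p = 2.25e-23; 14 higher adjusted over the list alone). Its median gene stood at 1.64 and 0.923 times the free RNA of knockouts and wild types. MHC class I rose (13 genes, median 0.32; adjusted p = 1.01e-06, and 0.331 with an estimated correlation), and the macrophage polarisation list was not called in this class. EdgeR quasi-likelihood called 12 genes higher and 2 lower of 11091. The count was 4, 21 and 84 without knockout replicates 1, 3 and 4 and 8, 7 and 7 without wild-type replicates 2 to 4.

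In dendritic-like cells edgeR quasi-likelihood called 14 genes higher and 3 lower of 10185. Its cluster was named from 10 markers, none among its 10 leading genes. Beside Nr4a1, Bmf, a pro-apoptotic BH3-only gene, fell from 74.7 ± 15.9 to 37.7 ± 6.599 CPM (log2 −1.07, SE 0.18, adjusted p = 0.00915), at 2.19 and 4.16 times the free RNA of knockouts and wild types. The epithelial progenitor factor Sox9 fell from 46.8 ± 13.2 to 20.8 ± 3.51 CPM, and the immunoglobulin segment Igkv8-24 rose from 6.22 ± 2.36 to 64.2 ± 22.5 CPM (adjusted p = 1.06e-06). Both lay below their free-RNA levels (0.238 and 0.264 times in knockouts). Ly6c1, a marker of monocytes and of endothelium, rose from 41.3 ± 14.2 to 133 ± 31.2 CPM, also below free RNA (0.742 times). Serpina3n and Capn13, a calpain protease gene, rose by log2 1.55 and 1.47 at 0.397 and 0.454 times the free RNA. The interferon list rose (26 genes, median 0.40, adjusted p = 1.88e-09, and 0.321 with an estimated correlation), against a median of 0.62 in free RNA. With called doublets kept, 6 genes were called; without knockout replicates 1 and 3 the count was 4 and 26, and without wild-type replicates 1, 2 and 3 it was 72, 11 and 3.

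Fibroblast-like cells had the most single-gene calls, 20 higher and 4 lower of 12895 by edgeR quasi-likelihood, and 8 of the higher ones were enriched in macrophage/monocyte-like over fibroblast-like cells. The complement gene C1qa rose from 51.8 ± 2.98 to 107 ± 20.9 CPM (log2 1.04, adjusted p = 0.0141), the mannose receptor Mrc1 from 30.1 ± 2.89 to 58.1 ± 8.22 (0.95, adjusted p = 0.0141) and the complement receptor C3ar1 from 4.14 ± 0.453 to 11.5 ± 2.35 CPM (1.44, adjusted p = 0.0250). Csf2rb2, Gpr65 and Serpina3f rose as well (log2 1.37, 1.65 and 2.11). The macrophage polarisation list rose (17 genes, 16 positive, median 0.94; camera adjusted p = 4.11e-22). It was 1 of 2 list calls in the data that held with an estimated correlation (adjusted p = 0.0322). It had 3 genes higher over all genes tested and 11 adjusted over the list alone, its median gene stood at 0.716 times the free RNA of knockouts, and free RNA was higher by 0.69. Of the falls, the secreted protease Adamts18 went from 11.8 ± 5.70 to 0.998 ± 0.436 CPM (log2 −3.44, SE 0.47, adjusted p = 0.0168; 8.01 times its free-RNA level in wild types). The ribonuclease angiogenin (Ang) fell from 52.9 ± 6.23 to 29.2 ± 1.62 CPM (log2 −0.84, SE 0.11), and Knop1 and Trim30d by −1.09 and −2.91. The stromal niche list fell (28 genes, 6 positive, median −0.18; adjusted p = 0.000876, and 0.21 with an estimated correlation; 2 lower adjusted over the list alone and 0 over all genes), with Bmp4 at 668 ± 61.7 against 896 ± 37.8 CPM and Wnt5b at 116 ± 12.7 against 165 ± 16.2 CPM. With called doublets kept 0 of the fibroblast-like genes passed edgeR quasi-likelihood. The count was also 0 without knockout replicate 1, 15 without knockout replicate 2, 188 without knockout replicate 4, 0 without wild-type replicate 2 or 3 and 12 without wild-type replicate 4.

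Serpina3n was higher and Gvin1 lower in the blood endothelial-, lymphatic endothelial- and glia-like cells of knockouts. In blood endothelial-like cells Serpina3n (ENSMUSG00000021091) rose from 40.7 ± 9.17 to 251 ± 69.7 CPM (log2 2.57, SE 0.23, adjusted p = 1.58e-05) and complement C4b from 31.4 ± 10.8 to 132 ± 46.8 CPM (log2 1.99, SE 0.29, adjusted p = 0.0145). Serpina3n and C4b, which are among the 10 leading genes of a fibroblast-like cluster, stood at 1.38 and 1.27 times the free RNA in knockouts and 0.654 and 0.610 times in wild types. Capn13 and Serpina3g rose there by log2 1.38 and 1.36, at 0.679 and 0.751 times the free RNA of knockouts. In lymphatic endothelial-like cells Serpina3n rose from 108 ± 18.7 to 317 ± 29.7 CPM (log2 1.53, SE 0.17, adjusted p = 8.38e-06). Both Serpina3n calls were kept in every alternative. Ly6c2, Ly6c1 and the zymogen granule gene Sycn rose in the lymphatic class by log2 1.64, 1.39 and 1.18, all below free RNA (0.48, 0.504 and 0.647 times in knockouts). The macrophage polarisation list rose in the lymphatic class also with an estimated correlation (9 genes, median 0.74, adjusted p = 0.0289), at 0.844 times the free RNA of knockouts. In glia-like cells Serpina3n had 373 ± 44.0 against 113 ± 56.2 CPM (adjusted p = 0.00883). The largest rises there were in Sst, a peptide of neurons and enteroendocrine cells, and in the endothelial marker Pecam1 (log2 2.73 and 2.34, adjusted p = 0.0410 each), which went from 0.318 and 0.321 times the free RNA in wild types to 1.74 and 1.13 times in knockouts. DESeq2 gave no adjusted p for Pecam1. Complement C3 had 214 ± 60.8 against 45.3 ± 21.0 CPM (log2 2.20, adjusted p = 0.00133), 1.72 and 0.619 times the free RNA, and Gpnmb 175 ± 65.7 against 53.9 ± 24.1 CPM (adjusted p = 0.0134), 18.5 and 9.44 times. C1qb, Adamdec1, H2-Ab1 and H2-Eb1, which are highest in other cell types, were among the calls too, at 0.472 to 0.575 times the free RNA in wild types and 0.788 to 1.17 times in knockouts. Gfap, a marker of glia, was also called, at 804 ± 24.2 against 278 ± 114 CPM (log2 1.47, adjusted p = 0.0134), 133 and 182 times the free RNA. In the same class Wnt6 fell from 117 ± 18.0 to 32.8 ± 21.0 CPM (adjusted p = 0.0410, not called by DESeq2) and Col20a1 from 195 ± 41.2 to 55.3 ± 28.3 CPM (n = 3 knockout and 4 wild-type libraries). The pericyte gene Rgs5 rose in interstitial cell of Cajal-like cells from 327 ± 51.4 to 651 ± 74.4 CPM (adjusted p = 0.0388) and Sycn from 585 ± 187 to 1451 ± 422 CPM, 0.815 times the free RNA; that class was named from 4 markers, none among its 10 leading genes. EdgeR quasi-likelihood calls numbered 11, 7, 15, 3 and 2 in the blood endothelial-, lymphatic endothelial-, glia-, interstitial cell- and smooth muscle-like classes, and 0 of 12013 in neuron-like cells, with 265 at an unadjusted p under 0.05 and 1 by DESeq2. The blood endothelial-like count was 3 without knockout replicate 1 or 2, 17 without knockout replicate 4, 5 without wild-type replicate 2 and 7 without wild-type replicate 3 or 4. The glia-like count was 5, 6, 4 and 6 without knockout replicates 1 and 2 and wild-type replicates 1 and 3, and 10 without wild-type replicate 4. With called doublets kept it was 4, all of them lower, so the rises named in glia-like cells lost their calls. The lymphatic endothelial-like count was 14 without knockout replicate 4, and 3, 3 and 4 without wild-type replicates 1 to 3. The interstitial cell-like count was 1 without knockout replicate 2 or wild-type replicate 1, 3 or 4. The smooth muscle-like count was 0, 8 and 0 without knockout replicates 1, 3 and 4 and 1, 0, 0 and 0 without wild-type replicates 1 to 4.

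**Figure D3:**
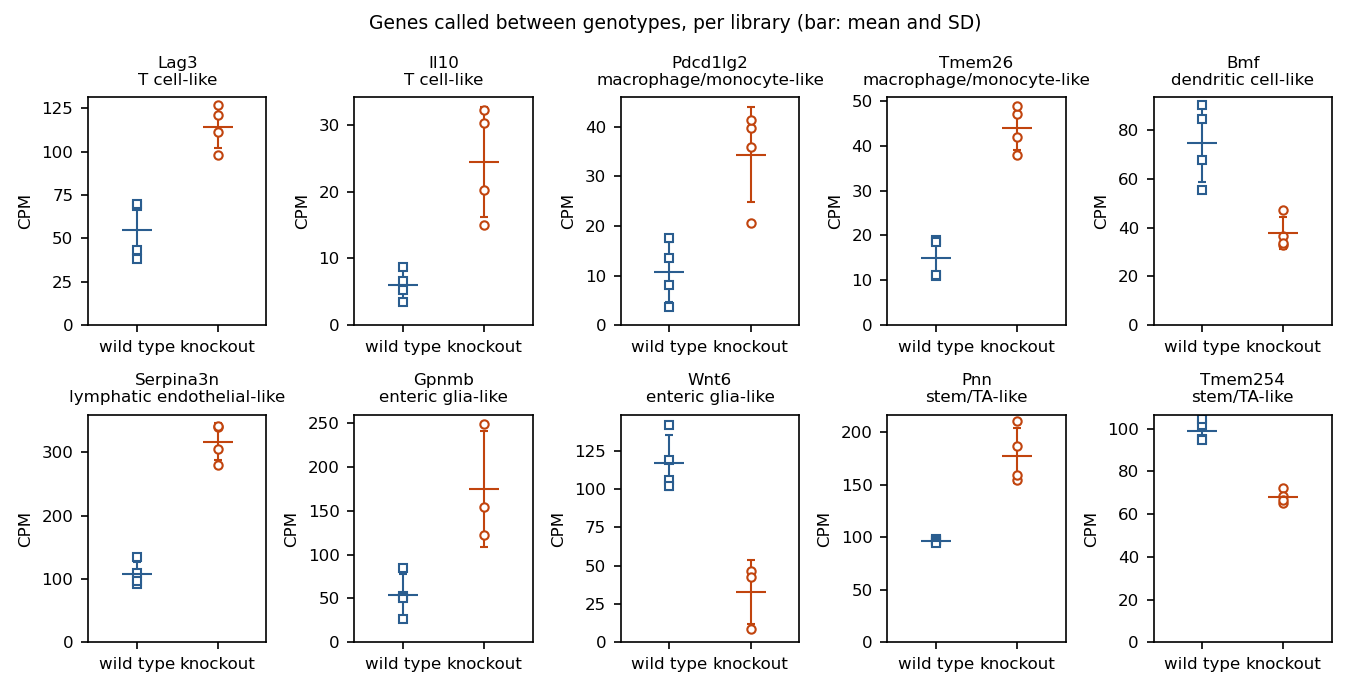
Expression in CPM of 10 called genes in the class named above each panel, with 1 point per library, wild types as squares and knockouts as circles, and bars for the mean and SD. In each panel the genotypes do not overlap, as for Tmem26 with 43.9 ± 4.95 CPM in knockouts and 14.9 ± 4.46 CPM in wild types.

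A few genes recur across classes. The 115 calls over the classes fall on 81 genes. Pnn (chromosome 12, 59066884 to 59073998) rose in 9 classes, Gvin1 (chromosome 7, 106156556 to 106215326) fell in 8 and Serpina3n (chromosome 12, 104406729 to 104414329) rose in 6, while B2m rose and Nr4a1 fell in 3 classes each. Free RNA moved the same way: Pnn had 184 CPM there in knockouts and 92.5 in wild types, Gvin1 58.0 and 181, and Serpina3n 182 and 62.2 CPM. Gvin1 lay below free RNA in both genotypes in 7 of its 8 classes, Serpina3n in 3 of 6 and Pnn in 2 of 9. Of the genes called in 2 classes, Trim12a and Trim30d lie on chromosome 7 near Gvin1, and Ly6a and Ly6c1 lie together on chromosome 15. Gvin1 in the whole colon had 20.9, 20.9, 107 and 16.5 CPM in knockout replicates 1 to 4 against 133, 142, 149 and 158 in the wild types, so knockout replicate 3 stood near the wild types. Trim30d had 1.29, 1.14, 15.7 and 0.502 CPM against 14.5, 12.3, 12.3 and 16.2, with the same replicate inside the wild-type range.

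**Figure D4:**
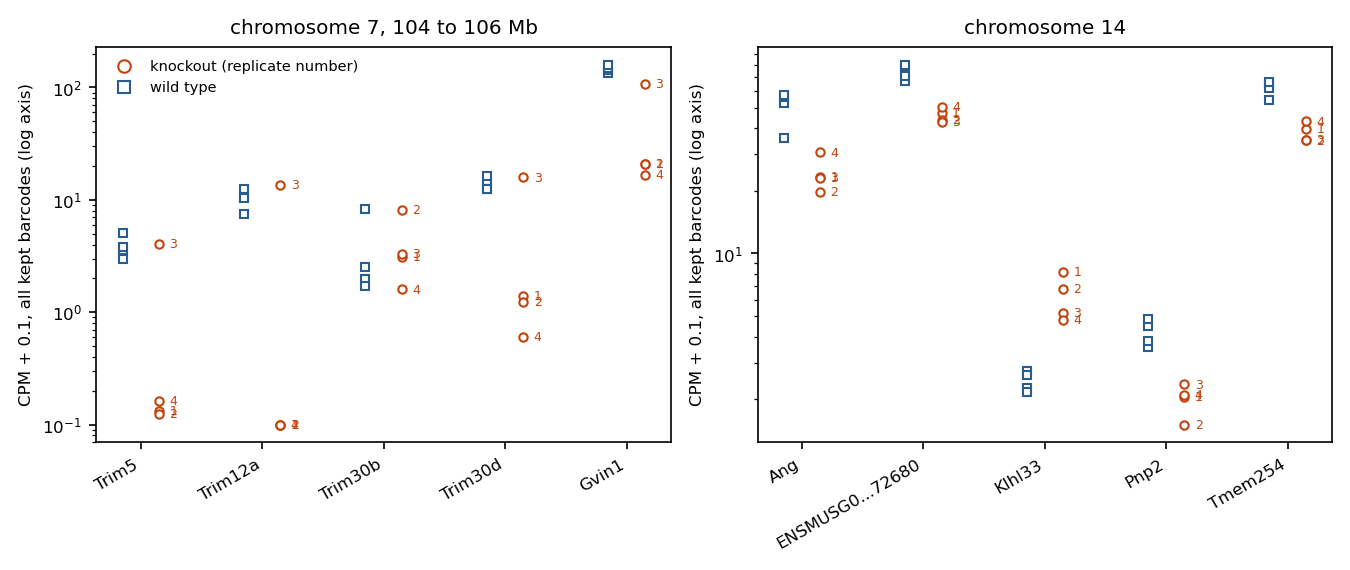
Expression in CPM plus 0.1 on a log axis, over all kept barcodes, of neighbouring called genes on chromosome 7 and on chromosome 14, with wild types as squares and knockouts as circles with their replicate number. For Trim5, Trim12a, Trim30d and Gvin1 knockout replicate 3 lies at or near the wild types and the other knockouts below, while Trim30b overlaps.

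No share of cells passed the test after adjustment, in a design where 1 class that separates completely reaches an adjusted p of no less than 0.0857 among the 3 compartments, 0.143 in a family of 5 classes and 0.2 in the family of 7. The adjusted test could therefore not call 1 class alone. By edgeR on the cell numbers 0 passed as well, with the smallest adjusted p at 0.110. Immune-like cells made up 37.2 ± 11.2% of named cells in knockouts and 26.2 ± 7.16% in wild types, epithelial-like cells 35.9 ± 7.74 and 40.7 ± 8.31%, and stromal and other cells 26.9 ± 5.31 and 33.1 ± 3.06% (SD, n = 4 each; exact permutation test, two-sided, p = 0.171, 0.4 and 0.114, adjusted 0.257, 0.4 and 0.257). Stem/TA-like cells were 31.8 ± 6.26% of the epithelium in knockouts and 38.2 ± 4.91% in wild types (exact permutation p = 0.2, adjusted 0.821), absorptive colonocyte-like cells 28.7 ± 7.84 and 25.9 ± 5.68%, and goblet-like cells 35.5 ± 6.14 and 32.1 ± 2.47%. Among immune cells, T cell-like cells were 12.9 ± 3.82 and 17.0 ± 2.42% (p = 0.171 by the same exact test) and B cell-like cells 24.7 ± 25.3 and 16.3 ± 19.8%, with knockout replicate 2 at 62.5% and wild-type replicate 1 at 46.0%. Fibroblast-like cells were 48.6 ± 11.5 and 37.6 ± 2.45% of the stroma and smooth muscle-like cells 26.7 ± 9.61 and 36.1 ± 2.56% (exact permutation p = 0.114 and 0.0571, adjusted 0.24 each). The smallest p that the 70 assignments can give is 0.0286. Without knockout replicate 3 the difference (knockout minus wild type) went from −6.43 to −3.30 points for stem/TA-like, from 11.1 to 5.90 for fibroblast-like and from −9.43 to −5.05 for smooth muscle-like cells. Without knockout replicate 2 it went from 11.1 to 5.78 for immune-like, from −6.28 to −4.18 for stromal and other cells and from 3.39 to 1.25 for goblet-like cells, which had 6.11 without knockout replicate 4. For epithelial-like cells it went from −4.79 to −1.61 and −7.59 without knockout replicates 2 and 3 and to −8.39, −3.19 and −2.13 without wild-type replicates 1, 3 and 4. For absorptive colonocyte-like cells it went from 2.78 to 6.03, 0.205 and 1.20 without knockout replicates 2 to 4 and to 1.29, 1.01, 4.20 and 4.62 without wild-type replicates 1 to 4. Leaving out 1 library turned the direction of the shares of B cell-, dendritic-, macrophage/monocyte-, plasma cell-, enteroendocrine-, tuft- and lymphatic endothelial-like cells, none of which was called.

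**Figure D5:**
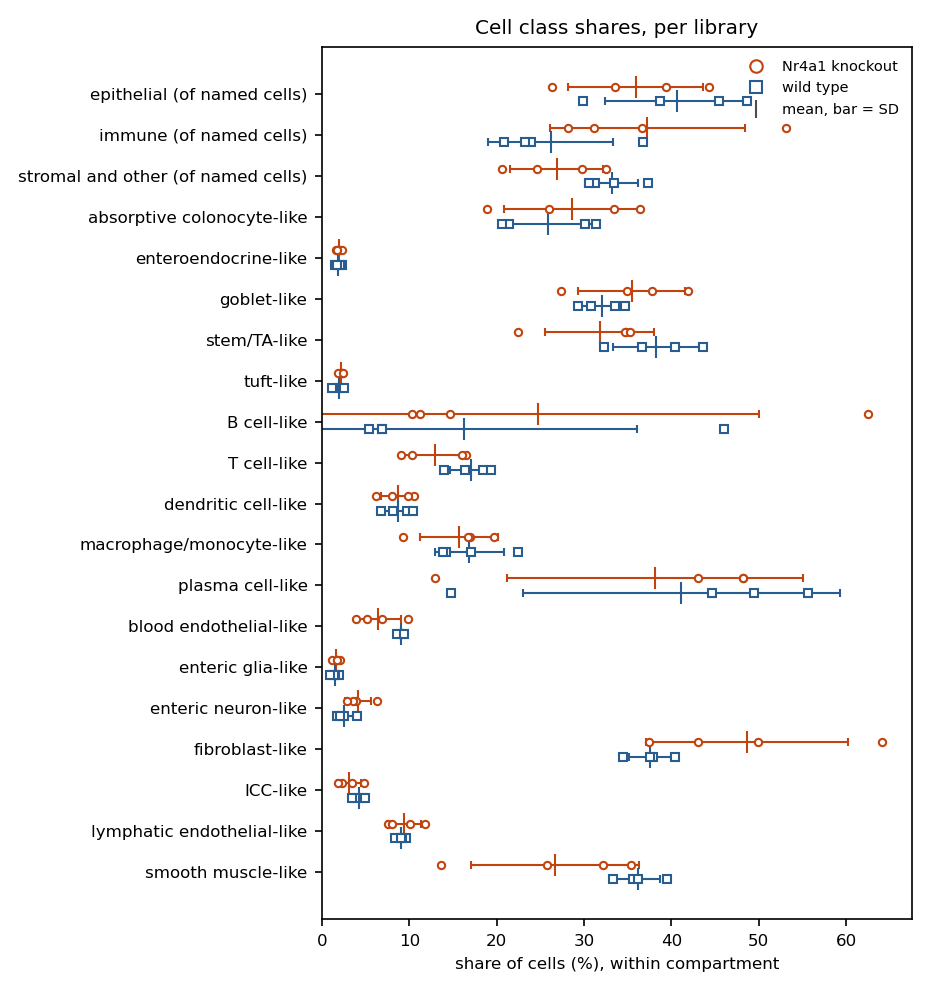
Share of cells in percent (horizontal axis) of each compartment among named cells and of each class within its compartment, with knockouts as circles, wild types as squares, means as vertical lines and SDs as bars. Stem/TA-like cells make up 31.8% of the epithelium in knockouts and 38.2% in wild types on average, with overlapping libraries.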

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

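The tests of where the called genes lie on the chromosomes were all chosen after the result was seen. Of 204 groups of libraries tested, 19 had a library standing apart from the others of its genotype, and chance gives about 1 group in 20.

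Several genes called in more than 1 class lie beside each other, and on chromosome 7 knockout replicate 3 stands apart in most classes where they were called. Gvin1 in this replicate held 167 CPM in T cell-like, 26.0 in absorptive colonocyte-like, 104.2 in blood endothelial-like and 71.7 in smooth muscle-like cells, Trim5 15.2 CPM in T cell-like, Trim30d 18.0 CPM in macrophage/monocyte-like and Trim30b 75.3 CPM in B cell-like cells, each far above the other knockouts, but Gvin1 in its 28 enteroendocrine-like cells was the lowest of the knockouts (7.56 against 14.3 to 28.4 CPM). Of the 14 recurrent genes other than Nr4a1, 5 lay within 3 Mb of another; they were seen before they were counted and are in part tandem families (Ly6, Trim). Over all 80 called genes 34 did (permutation test with random sets of tested genes, p = 0.0064, median 20), but outside the groups on chromosomes 7, 14 and 15 seen first 21 of 67 did (p = 0.104 by the same permutation test, median 14), so random places stay open. DNA flanking the targeted gene as the whole cause is argued against by 3 of these 5 on another chromosome than Nr4a1, but it stays open for genes on chromosome 15, where 2 of 80 called genes lay within 20 Mb (p = 0.392 by the same permutation test, median 1), Itgb7 at 0.959 Mb and Fbln1, and Ly6a, Ly6c1, Ly6c2 and Csf2rb2 farther off. For 4 of the 5 chromosome 7 genes knockout replicate 3 lay at or near the wild-type level of the whole colon with the other knockouts far below, which argues against loss of Nr4a1 in each knockout as the cause for these genes. Strain variants carried by part of the knockout line stay open for the chromosome 7 genes. In 2 of 13 classes, dendritic-like and macrophage/monocyte-like cells, a library held genes at both levels. Both were mixed only through Trim30b, which overlaps between genotypes in the whole colon. Of the 5 chromosome 14 genes with another called gene within 3 Mb, 0 had a knockout inside the wild-type range. These are Ang, ENSMUSG00000072680, Klhl33, Pnp2 and Tmem254. They were called between the same libraries, so part of this separation follows from that choice. For these 5 genes loss of Nr4a1 and a variant near them in the knockout line cannot be told apart.

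The other results with a library apart are given as values. Stem/TA-like cells made up 22.4% of the epithelium in knockout replicate 3, below the other knockouts. B cell-like cells made up 62.5% of immune cells in knockout replicate 2 and 46.0% in wild-type replicate 1, and plasma cell-like cells 12.9% in knockout replicate 2. In fibroblast-like cells Adamts18 had 1.65 CPM in knockout replicate 1, Gpr65 7.63 CPM in knockout replicate 4 and Knop1 12.5 CPM in knockout replicate 3. Pnn had 116 CPM in absorptive colonocyte-like and 322 CPM in smooth muscle-like cells of knockout replicate 1. Ccl8 in T cell-like cells had 11.7 CPM in wild-type replicate 4. Nr4a1 in wild-type replicate 4 was 25.5 CPM in glia-like cells, below the other wild types, and 167 CPM in neuron-like cells, above them.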

How the results depend on the processing

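Leaving out empty-like droplets, leaving out knockout replicate 2 and wild-type replicate 1 (rich in follicle B cells), adding the Lama3-led cluster to the absorptive colonocyte-like class, counting only genes at or above the free-RNA level, and shares of unnamed clusters per barcode that is not empty-like were chosen after seeing the data; the other alternatives were planned. Gene counts kept within 1.5 times under DESeq2 size factors, at least 50 cells per library and, for the whole colon, without empty-like droplets. No named gene reversed. Of the 65 calls of named genes, Nr4a1 included, 31 were kept and 34 lost with doublets kept, 281 kept and 223 lost summed over the single libraries left out, and 62 kept and 3 lost under the DESeq2 Wald test, which gained 3. Where a cause is not named it was not tested; fewer samples are by construction part of the cause when libraries are left out, and more genes tested when no filter is used. Knockout replicate 3 held 4740 kept barcodes before the removal of doublets, and its 11 glia-like cells were too few to be used. At Leiden resolution 1 no dendritic-like class was formed, so that class has no value there. The stem/TA-like class then held only a cluster led by Kcnq1. A cluster of higher UMI counts led by Cd177 and Spink4 matched stem/TA best but stayed unnamed. The stem/TA-like count there, 2 of 11673 genes with 1 shared with the main fit, thus comes from a different set of cells.

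Against the main counts of genes called by edgeR, the DESeq2 Wald test called 224 in the whole colon and, in the -like classes, 8 in B cells, 13 in T cells, 92 in absorptive colonocytes, 28 in dendritic cells, 1 in neurons, 4 in enteroendocrine cells, 170 in fibroblasts, 17 in goblet cells, 46 in macrophages, 36 in plasma cells, 10 in smooth muscle, 78 in stem/TA and 3 in tuft cells, 541 in all where edgeR had 115. Nr4a1 in the whole colon passed it at a log2 fold of −0.96. Without a filter on low counts there were 24 in T cells, 11 in absorptive colonocytes, 24 in blood endothelium, 57 in dendritic cells, 49 in glia, 10 in enteroendocrine cells, 1 in goblet cells, 16 in interstitial cells, 24 in lymphatic endothelium, 39 in macrophages, 6 in plasma cells and 4 in smooth muscle, 296 in all, and 1 for the difference between stem/TA and absorptive colonocytes.

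With the replicate number of the titles as a block there were 2 in the whole colon, 5 in T cells, 34 in absorptive colonocytes, 26 in dendritic cells, 8 in glia, 2 in enteroendocrine cells, 1 in goblet cells, 80 in macrophages, 4 in plasma cells, 4 in smooth muscle and 14 in stem/TA, 230 in all. The correlations of equal numbers were −0.0227, −0.0728, 0.177 and 0.138 against highest values with another number of 0.137, 0.606, 0.366 and 0.407, so the numbers do not pair the libraries.

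With at least 1000 UMIs per cell there was 1 gene in B cells, 6 in glia, 3 in plasma cells, 4 in smooth muscle and 1 in stem/TA, and the knockout minus wild-type share turned to 0.0295 points for dendritic cells and 0.655 for macrophages. With doublets kept there was 1 in B cells, 3 in absorptive colonocytes, 6 in dendritic cells, 4 in glia, 3 in enteroendocrine cells, 0 in fibroblasts, 11 in lymphatic endothelium, 1 in smooth muscle, 4 in stem/TA and 1 in tuft cells, 70 in all, and shares turned to −0.00135 points for tuft cells, −0.0582 for glia and −0.101 for lymphatic endothelium. At Leiden resolution 1 there was 1 in absorptive colonocytes, 3 in enteroendocrine cells and 1 in goblet cells, and the enteroendocrine share turned to −0.164. With the Lama3 cluster there was 1 in absorptive colonocytes, and the enteroendocrine share turned to −0.0220. Without the 2 follicle-rich libraries there was 1 in the whole colon, 10 in B cells, 18 in T cells, 0 in absorptive colonocytes, 4 in blood endothelium, 53 in dendritic cells, 4 in glia, 0 in enteroendocrine cells, 1 in interstitial cells, 3 in plasma cells, 5 in smooth muscle and 0 in stem/TA. Among the main calls, genes at or above the free-RNA level numbered 2 in absorptive colonocytes, 5 in blood endothelium, 11 in dendritic cells, 0 in enteroendocrine cells, 14 in fibroblasts, 1 in interstitial cells, 3 in lymphatic endothelium, 9 in macrophages, 0 in plasma cells, 1 in smooth muscle and 1 in stem/TA, 70 in all. Of 247 list calls 2 held with an estimated correlation, and fry called 6 lists, 5 of them among the 247.

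Leaving out 1 library at a time gave 0 to 6 genes in the whole colon (6 without knockout replicate 3), 0 to 88 in B cells, 0 to 20 in T cells, 0 to 12 in absorptive colonocytes, 3 to 17 in blood endothelium, 3 to 72 in dendritic cells, 4 to 16 in glia, 1 to 6 in enteroendocrine cells, 0 to 188 in fibroblasts, 0 to 3 in goblet cells, 1 to 3 in interstitial cells, 3 to 14 in lymphatic endothelium, 4 to 84 in macrophages, 0 to 11 in plasma cells, 0 to 8 in smooth muscle, 0 to 13 in stem/TA and 0 to 2 for the difference between stem/TA and absorptive colonocytes. The sum of genes changed in each cell class ran from 29 (without knockout replicate 1) to 385 (without knockout replicate 4), and list calls from 214 to 267. The median of the mucus and goblet list in interstitial cells ran from −0.00875 to 0.38. Knockout minus wild-type shares ran from −0.0924 to 0.187 points for enteroendocrine cells, −0.0737 to 0.408 for tuft cells, −4.23 to 18.3 for B cells, −0.753 to 0.726 for dendritic cells, −2.57 to 0.907 for macrophages, −11.8 to 5.39 for plasma cells and −0.517 to 0.913 for lymphatic endothelium.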

Other observations

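Tests chosen after the result was seen are the comparison of the Il17rb-led cluster, the test of the stem cell list within stem/TA-like cells and the splits of the libraries; the other tests of the 2 patterns below were written before their result was seen.

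An unnamed cluster led by Il17rb, Gata3, Nmur1, Klrg1 and Il13, genes known from group 2 innate lymphoid cells and T helper 2 cells, had a higher mean share in knockouts. Empty-like barcodes made up 11.6% of kept barcodes in knockouts and 39.3% in wild types, so its share was taken of the other barcodes, where it was 1.27 ± 0.207% in knockouts and 0.852 ± 0.0753% in wild types. The knockouts held 1.45, 0.982, 1.39 and 1.27% and the wild types 0.850, 0.959, 0.809 and 0.791%, so the groups did not overlap but knockout replicate 2 and wild-type replicate 2 lay close (exact permutation test, two-sided, p = 0.0286, the smallest possible, and 0.0857 adjusted over the 3 unnamed clusters). Of all kept barcodes it made up 1.12 ± 0.263% and 0.524 ± 0.159% (p = 0.0286 by the same exact permutation test). The other unnamed clusters, led by Lama3 and by Zg16 with Spink1, had 8.40 ± 2.59 against 8.35 ± 4.33% and 1.15 ± 0.254 against 0.995 ± 0.363% of the barcodes that are not empty-like (p = 0.971 and 0.571 by the same exact permutation test).

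The Y-linked gene Ddx3y had 67.7, 78.5, 69.2 and 0.00678 CPM in knockout replicates 1 to 4 and 59.0, 56.4, 0.0473 and 64.9 CPM in wild-type replicates 1 to 4, so 1 library of each genotype lacks it. The labels give no sex, the animals seem to be of both sexes, and no term for sex was fitted. The MHC class I light chain B2m was higher over all genes tested in 3 classes, and in T cell-like cells it had 551 ± 69.7 against 368 ± 21.8 CPM (edgeR quasi-likelihood, adjusted p = 0.146). Enteroendocrine-like cells had a higher immediate early list (18 genes, median 0.30, camera adjusted p = 0.000631, and 0.468 with an estimated correlation). The transcription factor Irf4 in macrophage/monocyte-like cells had 134 ± 38.1 against 58.8 ± 12.7 CPM (adjusted p = 0.0509).

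Macrophage genes were higher in the fibroblast-like class of knockouts, where they made up 40% of the risen calls (8 genes, median log2 fold 1.21). Macrophage RNA in these barcodes predicts that macrophage-enriched genes outside the calls are higher as well, and the 50 most enriched had a median log2 fold of 0.986 (quartiles 0.82 to 1.23, 49 positive). Free RNA predicts the same between empty droplets, where the median was 0.654 (quartiles 0.457 to 0.824), so both may contribute. Higher expression by the fibroblasts themselves predicts an excess of the called genes over the enriched ones. The excess was 0.222 with a 95% bootstrap interval of −0.02 to 0.66, and this explanation stays open. The interval resamples genes, not libraries. The called genes were picked for their rise in the same fit, so part of any excess can come from that choice. Although 0.222 met the bound set beforehand against this explanation, its interval reaches past that bound.

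The intestinal stem cell list was lower in the whole colon of knockouts (median −0.39). A smaller share of stem/TA-like RNA goes with this: the class held 21.2 ± 5.03% of UMIs in knockouts and 29.0 ± 3.82% in wild types, a log2 ratio of −0.45 (exact permutation p = 0.0571). It is not an independent check, as the list shares members such as Lgr5 and Axin2 with the markers that named the class. Lower expression within stem/TA-like cells goes with the lower list too, by the rotation test fry of limma at 0.0276 unadjusted (adjusted p = 0.175, median −0.20). A larger share of RNA from empty-like droplets is argued against, as these held fewer of the UMIs in knockouts (1.91 against 7.65%) and the median without them was −0.42, while the non-immune share of UMIs was 75.6 against 84.8%, a log2 ratio of −0.16, so a part from immune RNA stays open. The design names genotype as the biological difference. The share of stem/TA-like cells was not called, nor was the list within them by fry after adjustment, and the tests do not separate cell number from expression.

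Other splits of the 8 libraries into 4 and 4 (7 into 3 and 4 for glia-like cells), 35 in each case, were fitted in the same way with edgeR. Taken class by class, the real split alone gave as many genes in blood endothelial-like (11 genes, highest of the other splits 4), glia-like (15 genes, highest other 4) and fibroblast-like cells (24 genes, highest other 7). This is 1 of 35 splits, the fewest possible, with no allowance for the 18 counts compared, so it cannot exclude chance. The glia-like count was 4 with doublets kept or without wild-type replicate 1, and the blood endothelial-like count 3 without knockout replicate 1 or 2. The fibroblast-like count was 0 with doublets kept or without knockout replicate 1 or wild-type replicate 2 or 3. Chance cannot be excluded for the other counts above 0 either, nor for the classes together. As many genes came from 2 of 35 splits for B cell-like (4 genes, highest other 18), absorptive colonocyte-like (6, highest other 20), dendritic-like (17, highest other 17), lymphatic endothelial-like (7, highest other 25), plasma cell-like (1, highest other 1), smooth muscle-like (2, highest other 24) and stem/TA-like cells (2, highest other 76). As many came from 3 splits for T cell-like (8, highest other 78), 4 for macrophage/monocyte-like (14, highest other 72), 5 for interstitial cell-like (3, highest other 14) and 7 for enteroendocrine-like cells (1, highest other 8). With 0 genes called, the outcome of 35 of 35 is fixed and tells nothing in the whole colon (highest other 1214) and in neuron-like (38), goblet-like (958) and tuft-like cells (1915). Over all classes with 8 libraries 4 splits gave at least the 100 genes of the real one (highest other 2882), and 3 gave at least its 219 list calls (highest other 254). The split of knockout replicates 1 to 3 with wild-type replicate 1 against the rest gave the most genes in the whole colon, stem/TA-like and macrophage/monocyte-like cells. Knockout replicates 1 to 3 with wild-type replicate 4 gave the most in goblet-like and tuft-like cells, and knockout replicates 1 and 4 with wild-type replicates 3 and 4 in T cell-like cells. This points to a structure among the samples other than genotype. Knockout replicate 4 and wild-type replicate 3, which lack Ddx3y, share a side in these splits. They do not in the highest other splits of plasma cell-like and glia-like cells.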
